A study of Mus musculus with 94 samples.

How the data were processed

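Lung RNA of female C57BL/6J mice was measured on 94 Agilent mouse arrays of 62976 spots, of which 3671 were controls. Sample RNA was labelled with Cy5 and a universal mouse reference RNA with Cy3 on every array, with no dye swap. Arrays were spread over 13 slides and 11 scan days, and 6 arrays of 1 slide were extracted with an older protocol. Per the file headers, Agilent Feature Extraction 11.0.1.1 gave the intensity of each spot as raw median signals with local background, and processed signals that it had background-subtracted and dye-normalized. The deposited files also held flags of 0 or 1 (unit other) for spots well above background, outlying or saturated. The authors' value table holds log2 ratios of sample over reference, and how they were normalized is not stated.

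Scanner files were taken as the source. Median signals were corrected with normexp (offset 50) against the median local background and normalized by loess within each array in limma 3.58.1 (R 4.3.3, data.table, version 1.17.8). The plan named mean signals, but the files held medians. Of 55681 probes, 28026 were given a symbol through their RefSeq transcript, and 27655 without one were left out, 16194 of them named only by genome position. The brightest probe stood for each of 21154 genes, 5681 of which had more than 1. A gene was tested if well above background on at least 80% of the arrays of a group, which left 15541 genes, 8108 of them above background on every array and 112 with a missing value.

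Groups were material, dose and day as the labels give them. One model with a mean per group was fitted over all arrays with limma, with slide as a random block (consensus correlation 0.11). P values were adjusted by Benjamini-Hochberg within each of 29 comparisons, and a gene passed at an adjusted p under 0.05. These were 16 comparisons with the control of the same day, 4 dose trends (linear in dose, per 162 µg), 7 comparisons between materials at the same dose and day, and 2 tests of whether the rGO effect changed with time. For 36 gene lists of inflammation, cell types, stress and metabolism, camera was run with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Fits were checked on simulated data made from these arrays for 3 of the comparisons.

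Groups, comparisons, gene lists, the threshold and most alternatives were chosen before the data were examined. Named genes were the 10 largest rises and 10 largest falls without overlap between arrays in the 7 comparisons of the highest dose per material and day, up to 4 members per list by smallest p, and a fixed panel. Not every gene so allowed is named, and some that did not pass and lay near 0 were left out after the alternatives had been run. Alternatives were no slide block, slide as a fixed block, processed signals, no normexp, quantile normalization of the average intensity (which leaves log ratios unchanged), Cy5 alone, no filter, a filter on all arrays, the mean over probes, the authors' value table, a trended robust variance, leaving out the older protocol, only the groups or the days compared, an adjusted p under 0.01, a fold of at least 1.5, and each array left out in turn. After the data were seen, the level of Neat1 or a clock score (Dbp minus Arntl) as a covariate, scan day as the block, the value table in scanner order, leaving out doubted arrays, and list medians with each array left out were added. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.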

Results

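Gene expression was measured in the lungs of female C57BL/6J mice given graphene oxide (GO, sheets of carbon carrying oxygen groups), reduced graphene oxide (rGO, in which much of that oxygen has been removed), carbon black (CB, carbon particles often used as a reference particle) or vehicle. Each of 94 arrays compared lung RNA, in Cy5, with a common mouse reference RNA, in Cy3. The arrays formed 19 groups by material, dose (0, 18, 54 or 162 µg per mouse) and day (1, 28 or 90). Control at day 1 and rGO 54 µg at day 1 held 4 arrays each, GO 18 µg at day 90 held 6, and every other group held 5. GO was present at 18, 54 and 162 µg on day 1, at 18 µg on day 28, and at 18 and 54 µg on day 90. rGO was present at 18, 54 and 162 µg on days 1, 28 and 90, and CB at 162 µg on day 90 alone. Between 26.1% and 76.8% of the Cy5 spots of an array lay well above background, and the number of arrays limits the precision. Genes were named by symbol through their RefSeq transcripts. The labels do not say that the arrays of a group came from separate mice, so p measures the spread between these samples, which may be technical. Log2 changes are given ± SE, list medians are log2 changes, and rose, fell or passed refers to an adjusted p under 0.05.

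**Figure D1:**
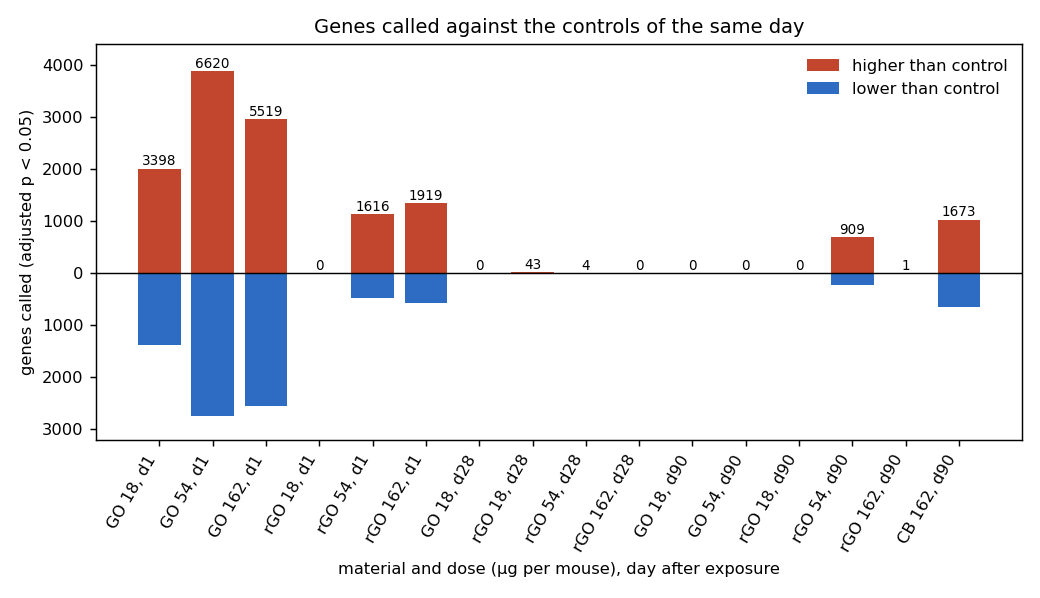
Genes past the threshold in each comparison with the control group of the same day, higher genes upward and lower genes downward, by material, dose and day. GO at day 1 has 3398, 6620 and 5519 genes at 18, 54 and 162 µg, while rGO 162 µg has 1919 at day 1 and 1 at day 90 (limma).

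The highest GO dose was compared with vehicle 1 day after exposure to ask how the lung responded early (5 GO and 4 control arrays). Mt2 and Mt1, metallothioneins that bind zinc and copper, rose by 4.87 ± 0.23 and 2.60 ± 0.16. Saa3, an acute phase apolipoprotein made in inflamed tissue, rose by 4.83 ± 0.48, and its relatives Saa2 and Saa1 by 3.04 ± 0.21 and 2.92 ± 0.30. Fkbp5, a chaperone cofactor induced through the glucocorticoid receptor, rose by 3.44 ± 0.16, and the clock gene Per1, another target of that receptor, by 2.22 ± 0.43. Timp1, an inhibitor of matrix metalloproteinases, rose by 3.80 ± 0.26, the protease inhibitor Serpina3m by 3.62 ± 0.28, and the lipoprotein lipase inhibitor Angptl4 by 3.39 ± 0.44. The remaining 4 of the 10 largest rises were in Map3k6 (3.20), Ch25h (3.20), the matrix protease Adamts4 (3.16) and Sprr1a (3.14). Among the largest falls, Colq changed by -2.36, Asgr1 by -2.23, Spon2 by -1.97, the cilium motor gene Dnah6 by -1.97, the airway secretory gene Scgb3a2 by -1.80 and Cr2, a complement receptor of B cells, by -1.76.

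Of 15 glucocorticoid-responsive genes tested, 15 rose (15 higher adjusted over the list alone). Their median was 2.22 (camera adjusted p = 6.0e-19, adjusted p = 2.3e-07 with an estimated correlation). Of 23 acute phase proteins tested, 15 rose and 8 did not pass (15 higher adjusted over the list alone). Their median was 1.12 (camera adjusted p = 3.2e-10, adjusted p = 0.0327 with an estimated correlation). Of 32 matrix and fibrosis genes tested, 14 rose, 3 fell and 15 did not pass (14 higher and 3 lower adjusted over the list alone). Their median was 0.20 (camera adjusted p = 0.00147, adjusted p = 0.264 with an estimated correlation), including Lox (2.36 ± 0.22) and Ccn2 (2.00 ± 0.20). Of 24 neutrophil markers tested, 13 rose and 11 did not pass (13 higher adjusted over the list alone). Their median was 0.86 (camera adjusted p = 1.3e-04, adjusted p = 0.264 with an estimated correlation), among them S100a8 (2.61 ± 0.52), Il1r2 (2.03 ± 0.29) and Mmp8 (1.61 ± 0.24). Of 25 cholesterol synthesis genes tested, 17 rose and 8 did not pass (17 higher adjusted over the list alone). Their median was 0.63 (camera adjusted p = 7.1e-08, adjusted p = 0.262 with an estimated correlation), with the mevalonate enzyme Pmvk at 2.15 ± 0.16 and the later enzyme Hsd17b7 at 1.64 ± 0.16. Of 18 ciliated cell markers tested, 12 fell and 6 did not pass (12 lower adjusted over the list alone). Their median was -0.77 (camera adjusted p = 2.1e-04, adjusted p = 0.598 with an estimated correlation), with Rsph1 at -1.24 ± 0.27 and Dnaic1 at -1.06 ± 0.20. Coagulation starter F3 rose by 2.86 ± 0.16, the alarmin Il33 by 1.87 ± 0.27, the chemokines Ccl7, Ccl2 and Ccl17 by 2.67, 2.11 and 1.95, and the iron-binding Lcn2 by 2.16, while the club cell enzyme Cyp2f2 fell by 0.94 (arrays overlapping).

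In limma, 5519 of 15541 genes passed, 2964 higher and 2555 lower. Of these, at least 1923 higher and 1624 lower genes had every GO array apart from every control array. Such counts, here and below, omit genes with provisional names, so they are lower bounds. Of all genes tested, to which the chance share refers, 26.5% lay apart (chance 1.59%). Called genes were selected on these arrays, so their counts and signs within slides, here and below, are no independent test. 5040 genes passed with slide as a fixed block, and 98.2% of the called genes had the same sign within each of the 2 slides that held both groups. The median of the glucocorticoid list was 2.18 with slide fixed and 2.17 to 2.60 within slides, that of the acute phase list 1.11 with slide fixed and 1.03 to 1.15 within slides, and that of the ciliated list -0.68 with slide fixed and -1.20 to -0.37 within slides. Among simulated values with independent normal noise, 94% of 2-fold changes were recovered and 1.64% of the calls were false.

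At 54 µg of GO on day 1 (5 GO, 4 control arrays), Saa3 rose by 6.67 ± 0.48, Mt2 by 4.92 ± 0.23, Timp1 by 4.42 ± 0.26 and Saa2 by 3.97 ± 0.21. The monocyte attractants Ccl7 and Ccl2 rose by 3.62 ± 0.49 and 2.98 ± 0.37, the T cell attractant Ccl17 by 2.58 ± 0.28 and the alarmin Il33 by 2.68 ± 0.27. Among 23 acute phase proteins tested, 18 rose and 5 did not pass (18 higher adjusted over the list alone). Their median was 1.28 (camera adjusted p = 2.7e-14, adjusted p = 0.00334 with an estimated correlation). Among 15 glucocorticoid-responsive genes tested, 11 rose and 4 did not pass (12 higher adjusted over the list alone). Their median was 1.80 (camera adjusted p = 5.0e-10, adjusted p = 0.00113 with an estimated correlation), with Fkbp5 at 2.90 ± 0.16. Among 25 cholesterol synthesis genes tested, 17 rose, 1 fell and 7 did not pass (17 higher and 1 lower adjusted over the list alone). Their median was 0.73 (camera adjusted p = 3.4e-07, adjusted p = 0.441 with an estimated correlation), with Pmvk at 1.89 ± 0.16. Il1r2, the decoy receptor of interleukin 1, rose by 3.04, F3 by 2.70, the DNA damage genes Gadd45g and Cdkn1a by 2.57 and 1.96, the lipid droplet coat Plin2 by 1.75 and the macrophage lectin Lgals3 by 1.43. Cyp2f2 fell by 1.35 and the smooth muscle gene Tagln by 0.97, the latter with overlapping arrays and -0.88 with slide fixed and -0.82 to 0.30 within slides. In limma, 6620 of 15541 genes passed, 3886 higher and 2734 lower, with 2661 of the higher and 1594 of the lower genes apart in every array (30.6% of all genes tested apart, chance 1.59%). 6205 genes passed with slide as a fixed block, and 93.7% of the called genes had the same sign within each of the 2 slides that held both groups. The acute phase median was 1.29 with slide fixed and 1.70 to 1.72 within slides, and the glucocorticoid median 1.62 with slide fixed and 1.46 to 1.84 within slides.

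The lowest GO dose on day 1 (5 GO, 4 control arrays) was led by Saa3 at 7.60 ± 0.48, Saa1 at 5.14 ± 0.30, Saa2 at 4.12 ± 0.21, the plasma glycoprotein Orm2 at 4.01 ± 0.32 and Timp1 at 4.11 ± 0.26. The neutrophil attractant Cxcl5 rose by 4.04 ± 0.65, Ccl7 by 3.68 ± 0.49, the eosinophil attractant Ccl24 by 3.61 ± 0.45 and Cxcl10, an interferon-induced T cell attractant, by 3.40 ± 0.50. Of 23 acute phase proteins tested, 15 rose and 8 did not pass (16 higher adjusted over the list alone). Their median was 1.04 (camera adjusted p = 3.4e-20, adjusted p = 3.1e-04 with an estimated correlation). Of 22 CC chemokines and monocyte attractants tested, 13 rose and 9 did not pass (15 higher adjusted over the list alone). Their median was 1.03 (camera adjusted p = 1.5e-10, adjusted p = 0.012 with an estimated correlation). Of 18 endoplasmic reticulum stress genes tested, 11 rose and 7 did not pass (11 higher adjusted over the list alone). Their median was 0.54 (camera adjusted p = 1.8e-06, adjusted p = 0.0223 with an estimated correlation), with the chaperones Sdf2l1, Hspa5 and Pdia6 at 1.44, 0.81 and 0.79. Of 29 interferon-stimulated genes tested, 21 rose and 8 did not pass (24 higher adjusted over the list alone). Their median was 0.91 (camera adjusted p = 4.7e-12, adjusted p = 0.187 with an estimated correlation), with Isg15 at 1.88 ± 0.35 and the nucleic acid sensor Zbp1 at 1.51 ± 0.25. Mt2 rose by 1.53, the heme-degrading Hmox1 by 1.11 and the replication genes Mcm2 and Mcm3 by 1.16 and 0.97, while the detoxifying enzymes Gsta2, Aldh1a1 and Gstm1 fell by 1.91, 1.51 and 1.30. Fkbp5 rose by 0.48 ± 0.16 but did not pass with slide as a fixed block. In limma, 3398 of 15541 genes passed, 2009 higher and 1389 lower, with 1383 of the higher and 874 of the lower genes apart in every array (18.8% of all genes tested apart, chance 1.59%). 3043 genes passed with slide as a fixed block, and 98.6% of the called genes had the same sign within each of the 2 slides that held both groups. The median of the acute phase list was 1.09 with slide fixed and 1.02 to 1.51 within slides, of the monocyte attractants 1.11 with slide fixed and 0.97 to 1.15 within slides, of the stress list 0.51 with slide fixed and 0.35 to 0.42 within slides, and of the interferon list 0.84 with slide fixed and 0.36 to 1.01 within slides.

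The dose trend asked which genes had a slope on GO dose on day 1, fitted over 0, 18, 54 and 162 µg and given per 162 µg. Mt2 rose with dose by 4.31 ± 0.20 and Fkbp5 by 3.32 ± 0.14. Saa3 had a slope of 1.66 ± 0.42 and Timp1 of 2.13 ± 0.23, but neither rose steadily, at 7.60, 6.67 and 4.83 (Saa3) and 4.11, 4.42 and 3.80 (Timp1) above control at 18, 54 and 162 µg. Isg15 fell with dose by 1.69 and Ccl24 by 1.96, although both were above control at 18 µg. Of 15 glucocorticoid-responsive genes tested in the trend, 15 rose (15 higher adjusted over the list alone). Their median was 2.07 (camera adjusted p = 5.9e-19, adjusted p = 2.3e-07 with an estimated correlation). Of 29 interferon-stimulated genes tested in the trend, 23 fell and 6 did not pass (24 lower adjusted over the list alone). Their median was -0.76 (camera adjusted p = 3.2e-07, adjusted p = 0.5 with an estimated correlation). In limma, 6482 of 15541 genes passed, 3257 higher and 3225 lower, and 6243 passed with slide as a fixed block.

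**Figure D2:**
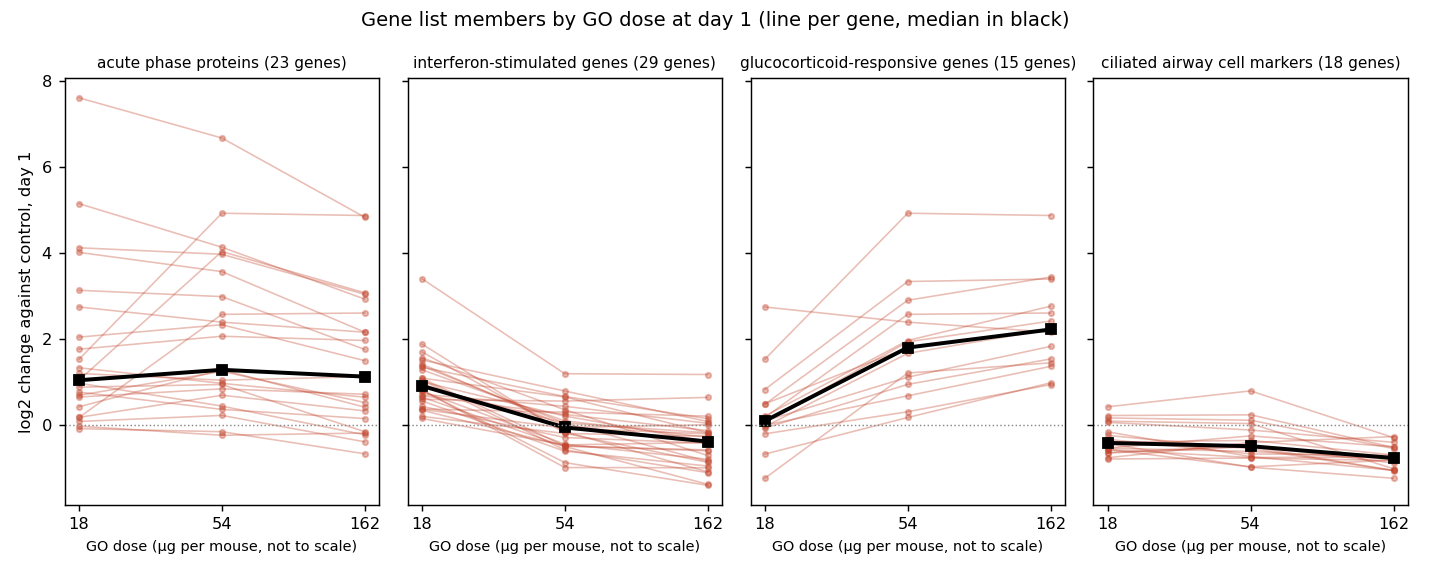
Log2 change against control at day 1 for each member of 4 gene lists at 18, 54 and 162 µg of GO, 1 line per gene and the list median in black. The glucocorticoid median goes from 0.092 at 18 µg to 1.80 at 54 µg and 2.22 at 162 µg, and the interferon median from 0.91 to -0.059 and -0.39.

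The highest rGO dose on day 1 (5 rGO, 4 control arrays) addressed the early response to the reduced material. Neat1, a long RNA that forms nuclear paraspeckles, rose by 2.58 ± 0.64, Meg3, another long noncoding RNA, by 2.43 ± 0.52, and Rsrp1 by 2.06 ± 0.44. The inhibitory myeloid receptors Lilrb4a and Cd300lf rose by 2.45 ± 0.39 and 2.17 ± 0.39, the macrophage lectin Chil3 by 2.41 ± 0.47, the neutrophil protein S100a8 by 2.08 ± 0.52 and the cytokine Il1b by 2.06 ± 0.47. The contractile genes Myl9, Tpm2, Acta2 and Des fell by 1.53, 1.51, 1.41 and 1.32 (Des did not pass with slide as a fixed block). Of 24 alveolar macrophage markers tested, 13 rose and 11 did not pass (14 higher adjusted over the list alone). Their median was 0.78 (camera adjusted p = 1.0e-07, adjusted p = 0.438 with an estimated correlation), with the proton pump subunit Atp6v0d2 at 1.68 ± 0.29, Ear1 at 1.73, Itgax at 1.30 ± 0.25 and Mrc1 at 1.04. Of 16 natural killer cell markers tested, 13 rose and 3 did not pass (15 higher adjusted over the list alone). Their median was 0.89 (camera adjusted p = 3.9e-10, adjusted p = 0.438 with an estimated correlation), with Klra8 at 1.97 ± 0.40 and Klrd1 at 1.54 ± 0.35. Of 18 T cell markers tested, 8 rose and 10 did not pass (10 higher adjusted over the list alone). Their median was 0.55 (camera adjusted p = 1.3e-05, adjusted p = 0.438 with an estimated correlation), with Lck at 1.02 ± 0.22. Of 20 smooth, cardiac and skeletal muscle markers tested, 7 fell and 13 did not pass (7 lower adjusted over the list alone). Their median was -1.08 (camera adjusted p = 1.4e-05, adjusted p = 0.46 with an estimated correlation). Saa3 rose by 1.52 ± 0.48, Lcn2 by 1.32 and Timp1 by 0.99, while the detoxifying Aldh1a1 and Gsta4 fell by 0.84 and 0.82. Arrays overlapped for Ear1, Lcn2 and Timp1, and Timp1 was at 0.61 without rGO replicate 4. No list of the 36 kept its call with an estimated correlation.

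In limma, 1919 of 15541 genes passed, 1351 higher and 568 lower, with 1030 of the higher and 356 of the lower genes apart in every array (chance 1.59%). 1553 genes passed with slide as a fixed block, and 98.9% of the called genes had the same sign within each of the 2 slides that held both groups. The alveolar macrophage median was 0.72 with slide fixed and 0.29 to 1.29 within slides, the natural killer median 0.85 with slide fixed and 0.64 to 1.06 within slides, and the muscle median -0.89 with slide fixed and -1.90 to -0.40 within slides. The count was 729 without control replicate 3, 1073 without rGO replicate 4 and 1038 without control replicate 4, and 0 in limma with Neat1 as a covariate (1394 at an unadjusted p under 0.05).

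At 54 µg of rGO on day 1 (4 rGO, 4 control arrays), S100a8 rose by 2.18 ± 0.54, Saa3 by 1.88 ± 0.50, Il1b by 1.78 ± 0.49, Lcn2 by 1.28 ± 0.27 and Klrd1 by 1.35 ± 0.37. Without rGO replicate 4, an array nearer to the CB group than to its own, Saa3 was at 1.13 and did not pass. Among 24 alveolar macrophage markers tested, 11 rose and 13 did not pass (14 higher adjusted over the list alone). Their median was 0.77 (camera adjusted p = 4.9e-07, adjusted p = 0.568 with an estimated correlation), with Atp6v0d2 at 1.59 ± 0.30 and Itgax at 1.21 ± 0.26. Lck, a kinase of T cells, rose by 1.05 ± 0.24. Acta2 and Tagln fell by 1.36 and 1.16, the matrix protein Sparc by 0.88 and the collagen gene Col1a1 by 0.67. In limma, 1616 of 15541 genes passed, 1134 higher and 482 lower, with 939 of the higher and 355 of the lower genes apart in every array (chance 2.86%). 1430 genes passed with slide as a fixed block, and 99.1% of the called genes had the same sign within each of the 2 slides that held both groups, with alveolar macrophage medians of 0.67 with slide fixed and 0.54 to 0.84 within slides. The count was 455 without control replicate 3, 952 without rGO replicate 3, 793 without control replicate 4 and 993 without rGO replicate 4, and 0 in limma with Neat1 as a covariate (1401 at an unadjusted p under 0.05).

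At 18 µg of rGO on day 1 (5 rGO, 4 control arrays), no gene passed. The clock output gene Dbp differed by 1.65, the natural killer receptor gene Klre1 by 0.67 and the chaperone Hsp90aa1 by -0.66, with adjusted p of 0.292, 0.292 and 0.219. Limma gave 0 genes at the threshold and 1713 at an unadjusted p under 0.05, with 0 with slide as a fixed block. Leaving out 1 array gave 1 without rGO replicate 1 and 2 without control replicate 2, and without the 6 arrays of the older protocol Hsp90aa1 alone passed (-0.66).

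Over 0, 18, 54 and 162 µg of rGO on day 1, Chil3 rose with dose by 2.02 ± 0.41 per 162 µg, Klra8 by 1.54 ± 0.35 and Saa3 by 1.52 ± 0.42, and Acta2 fell by 1.19. Of 24 alveolar macrophage markers tested in the trend, 10 rose and 14 did not pass (13 higher adjusted over the list alone). Their median was 0.74 (camera adjusted p = 4.7e-09, adjusted p = 0.387 with an estimated correlation). In limma, 1184 of 15541 genes passed, 834 higher and 350 lower, and 916 with slide as a fixed block. The count was 650 without rGO 162 µg replicate 1, 673 without rGO 18 µg replicate 1 and rGO 162 µg replicate 5 left out in turn, 669 without rGO 162 µg replicate 2, 410 without control replicate 3, 141 without rGO 162 µg replicate 4, 529 without rGO 18 µg replicate 3 and 697 without control replicate 4, and 21 with Neat1 as a covariate.

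**Figure D3:**
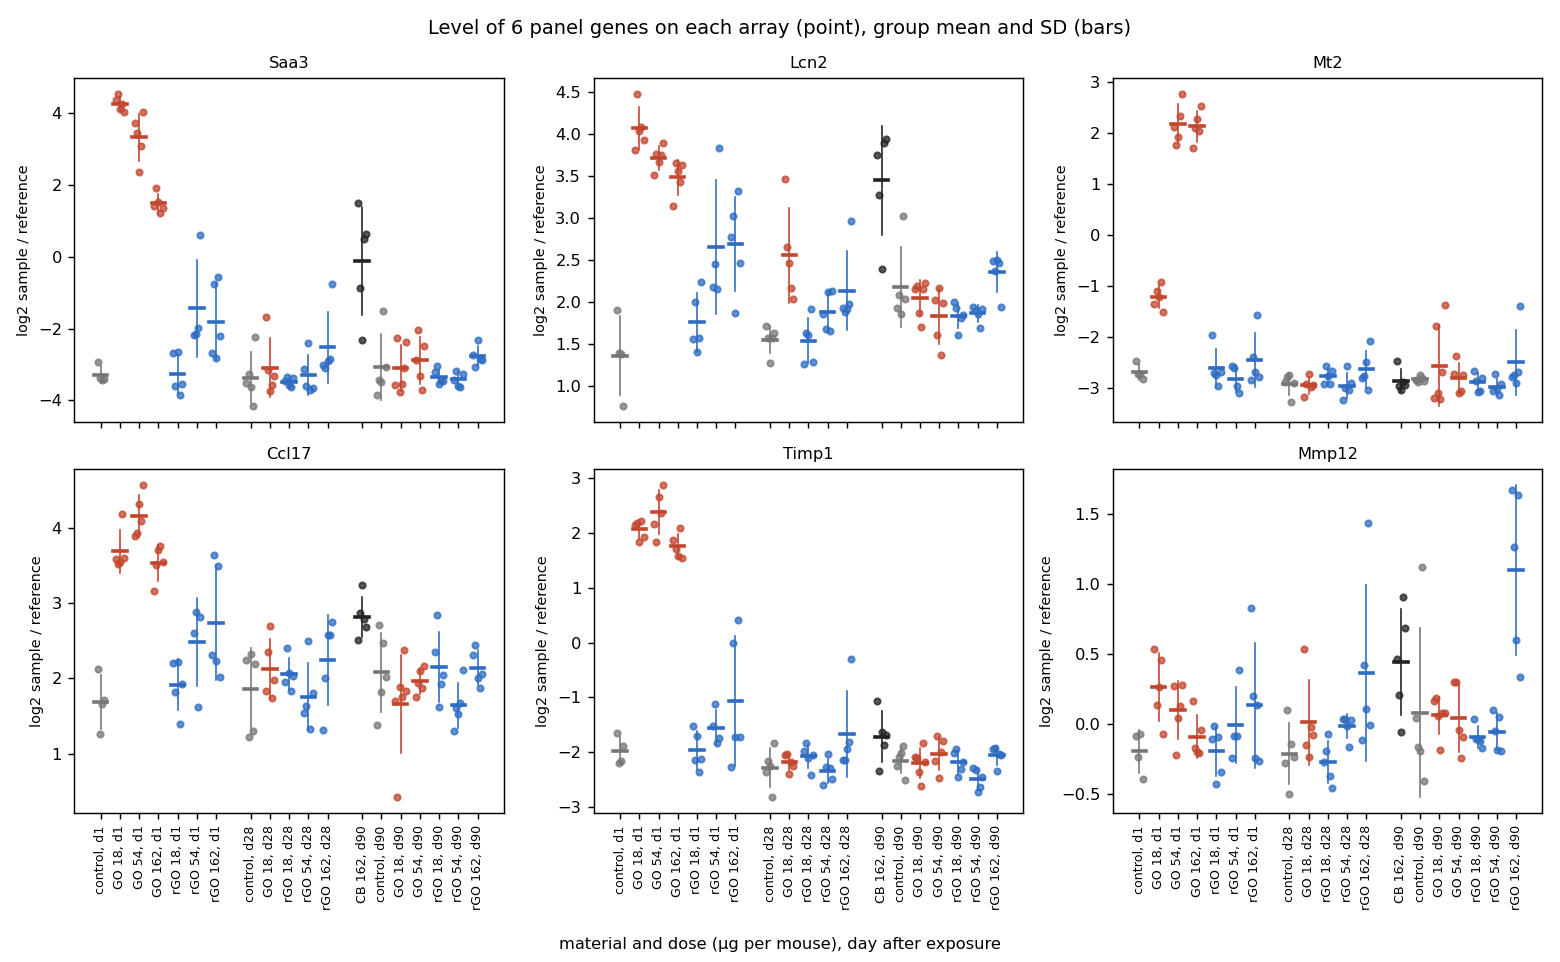
Log2 ratio to the reference RNA of Saa3, Lcn2, Mt2, Ccl17, Timp1 and Mmp12 on each array, by group, with the group mean and SD. Saa3 in the GO arrays of day 1 lies above every control array of day 1.

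GO and rGO were compared at each shared dose on day 1 to ask if the sheets differed. At 162 µg (5 and 5 arrays), GO was higher than rGO in Mt2 by 4.58 ± 0.22, Fkbp5 by 3.25 ± 0.15, F3 by 3.11 ± 0.16, Timp1 by 2.82 ± 0.25, Cdkn1a by 2.64 ± 0.18, the collagen crosslinker Lox by 2.39 ± 0.21 and the keratin Krt19 by 1.71 ± 0.15. It was lower in Cr2 (-2.08 ± 0.26), the interferon-induced Gbp4 (-2.08 ± 0.31), the natural killer receptor Klra4 (-1.66 ± 0.24), Lck (-1.46 ± 0.22) and Itgax (-1.23 ± 0.24). All 15 glucocorticoid-responsive genes tested were higher with GO (15 adjusted over the list alone). Their median was 1.55 (camera adjusted p = 2.2e-15, adjusted p = 6.1e-06 with an estimated correlation). Of 16 natural killer cell markers tested, 14 were lower with GO and 2 did not pass (14 adjusted over the list alone). Their median was -0.95 (camera adjusted p = 1.0e-05, adjusted p = 0.411 with an estimated correlation). It was -0.041 for GO and 0.89 for rGO against control. In limma, 6367 of 15541 genes passed, 3056 higher and 3311 lower, with 1916 of the higher and 2157 of the lower genes apart in every array (chance 0.794%) and 5766 with slide as a fixed block.

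At 54 µg (5 GO, 4 rGO arrays), GO exceeded rGO in Mt2 by 4.99 ± 0.23, Saa3 by 4.79 ± 0.49, Timp1 by 3.94 ± 0.27, Ccl2 by 2.92 ± 0.37, Fkbp5 by 2.46 ± 0.16 and Pmvk by 1.54 ± 0.16, and was lower in the T cell receptor gene Cd3g (-1.13 ± 0.18). Of 23 acute phase proteins tested, 15 were higher with GO and 8 did not pass (15 higher adjusted over the list alone). Their median was 0.97 (camera adjusted p = 1.7e-15, adjusted p = 0.00178 with an estimated correlation). Of 15 glucocorticoid-responsive genes tested at 54 µg, 10 were higher with GO and 5 did not pass (10 higher adjusted over the list alone). Their median was 1.21 (camera adjusted p = 5.3e-11, adjusted p = 4.6e-04 with an estimated correlation). In limma, 4171 of 15541 genes passed, 2362 higher and 1809 lower, with 1576 of the higher and 1034 of the lower genes apart in every array (chance 1.59%) and 3551 with slide as a fixed block.

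At 18 µg (5 and 5 arrays), GO exceeded rGO in Saa3 by 7.59 ± 0.46, Saa1 by 5.18 ± 0.29, Ccl24 by 3.80 ± 0.43, Ccl7 by 3.66 ± 0.47, Isg15 by 2.10 ± 0.33 and Hspa5 by 1.17 ± 0.13. Among 23 acute phase proteins tested at 18 µg, 14 were higher with GO and 9 did not pass (15 higher adjusted over the list alone). Their median was 1.14 (camera adjusted p = 9.8e-24, adjusted p = 5.1e-05 with an estimated correlation). Among 18 endoplasmic reticulum stress genes tested at 18 µg, 11 were higher with GO and 7 did not pass (12 higher and 1 lower adjusted over the list alone). Their median was 0.54 (camera adjusted p = 1.6e-13, adjusted p = 6.5e-05 with an estimated correlation). In limma, 1963 of 15541 genes passed, 1186 higher and 777 lower, with 765 of the higher and 413 of the lower genes apart in every array (chance 0.794%) and 1630 with slide as a fixed block. No slide held both groups in any of these 3 comparisons, and the 18 µg count was 1307 without rGO replicate 3.

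At day 28, comparisons asked what persisted. With 18 µg of GO (5 and 5 arrays) no gene passed, and the largest named differences were in Per1 (1.54 ± 0.40, adjusted p = 0.233), the macrophage glycoprotein Gpnmb (1.18 ± 0.47, adjusted p = 0.421), Lcn2 (1.02 ± 0.24, adjusted p = 0.105), the stress regulator Atf3 (0.92 ± 0.23, adjusted p = 0.193) and the lysosomal protease Ctsd (0.58 ± 0.19, adjusted p = 0.309). Limma gave 0 genes, 1419 at an unadjusted p under 0.05, 0 with slide as a fixed block over the 4 slides that held both groups, and 5 without GO replicate 5 and 3 without control replicate 5.

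With 18 µg of rGO at day 28 (5 and 5 arrays), Dbp rose by 1.72 ± 0.38, the clock repressors Nr1d1 and Nr1d2 by 0.94 ± 0.23 and 0.86 ± 0.18, the immediate early factor Klf4 by 1.18 ± 0.28, and the heat shock genes Hspa1a and Dnajb1 by 0.85 ± 0.18 and 0.66 ± 0.16. Nr1d1, Klf4 and Dnajb1 did not pass with slide as a fixed block, nor without the arrays of the older protocol, where 13 genes passed. Of 17 circadian clock genes tested, 3 rose and 14 did not pass (8 higher and 1 lower adjusted over the list alone). Their median was 0.44 (camera adjusted p = 1.9e-04, adjusted p = 0.335 with an estimated correlation), and 0.42 with slide fixed and 0.38 to 0.60 within slides. In limma, 43 of 15541 genes passed, 25 higher and 18 lower, with 23 of the higher and 13 of the lower genes apart in every array (chance 0.794%). 23 genes passed with slide as a fixed block, and 100% of the called genes had the same sign within each of the 4 slides that held both groups. The count was 12 without control replicate 1, 6 without rGO replicate 1, 8 without rGO replicate 2, 21 without rGO replicate 3, 9 without control replicate 4, 2 without rGO replicate 4 and 15 without rGO replicate 5, and 582 with a score of Dbp minus Arntl on each array as a covariate.

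With 54 µg of rGO at day 28 (5 and 5 arrays), limma called 4 genes, all higher. They were the gluconeogenic enzyme G6pc (1.15 ± 0.24), Igfbp1, a binding protein of insulin-like growth factors (above background on 0 control arrays), and, named after their values were seen, the RNA-binding genes Khdc4 (0.73) and Safb (0.64), both with overlapping arrays. Of all genes tested, 1.34% lay apart, where chance separates 0.794%, and 2203 genes had an unadjusted p under 0.05. Slide as a fixed block left 0 genes in limma, and 75% of the 4 had the same sign within each of the 4 slides that held both groups. Fitting only the 2 groups gave 0 in limma (1910 at an unadjusted p under 0.05), and leaving out the older protocol 48. Leaving out 1 array gave 603 without control replicate 1, 0 without control replicates 2 and 3 and rGO replicates 3 and 4 left out in turn, 652 without control replicate 4 and 1 without control replicate 5.

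With 162 µg of rGO at day 28 (5 and 5 arrays), limma gave 0 genes and 443 at an unadjusted p under 0.05. Of 15 glucocorticoid-responsive genes tested at this dose, none passed (6 higher adjusted over the list alone). Their median was 0.36 (camera adjusted p = 2.1e-06, adjusted p = 0.0331 with an estimated correlation), and 0.36 with slide fixed and 0.28 to 0.37 within slides. The steroid-induced Errfi1 (0.94 ± 0.29, adjusted p = 1) and Tsc22d3 (0.85 ± 0.28, adjusted p = 1), Lcn2 (0.60 ± 0.24, adjusted p = 1) and the macrophage protease Mmp12 (0.54 ± 0.20, adjusted p = 1) did not pass. With independent normal noise, 92% of simulated 2-fold changes were recovered (4.19% of calls false), which need not hold for real noise. Labels of rGO replicate 3 name both rGO and GO, and without it limma also gave 0 genes (368 at an unadjusted p under 0.05). The rGO dose trend at day 28 also gave 0 genes in limma (211 at an unadjusted p under 0.05). Of 18 endoplasmic reticulum stress genes tested in the day 28 trend, none passed (none adjusted over the list alone). Their median was 0.15 (camera adjusted p = 1.7e-07, adjusted p = 0.0148 with an estimated correlation).

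Between GO and rGO at 18 µg and day 28 (5 and 5 arrays), GO was higher in the lysosomal protease Ctss (1.31 ± 0.25), Atp6v0d2 (1.30 ± 0.27), Itgax (0.95 ± 0.23), the neutrophil receptor Cxcr1 (1.23 ± 0.26), Lcn2 (1.02 ± 0.24) and the T cell gene Cd3d (0.87 ± 0.22). Itgax, Lcn2 and Cd3d did not pass with slide as a fixed block, and of these 6 only Cxcr1 passed without the arrays of the older protocol (8 genes in all). Of 26 lysosome and lipid-laden macrophage genes tested, 3 were higher with GO and 23 did not pass (15 higher adjusted over the list alone). Their median was 0.40 (camera adjusted p = 2.9e-12, adjusted p = 0.0512 with an estimated correlation), and 0.40 with slide fixed and 0.16 to 0.49 within slides. Of 24 alveolar macrophage markers tested at day 28, 3 were higher with GO and 21 did not pass (13 higher adjusted over the list alone). Their median was 0.54 (camera adjusted p = 7.5e-13, adjusted p = 0.068 with an estimated correlation). In limma, 59 of 15541 genes passed, 57 higher and 2 lower, and 44 of the higher and 1 of the lower genes were apart in every array (chance 0.794%). 29 genes passed with slide as a fixed block, and 83.1% of the called genes had the same sign within each of the 4 slides that held both groups. The count was 0 without GO replicate 1 and rGO replicates 1 and 5 left out in turn, 13 without GO replicate 2, 23 without rGO replicate 2, 3 without GO replicate 3, 20 without rGO replicate 3, 185 without GO replicate 5 and 159 without rGO replicate 4.

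At day 90, 18 µg of GO (6 GO, 5 control arrays) gave 0 genes in limma and 3255 at an unadjusted p under 0.05. Of 18 ciliated cell markers tested at day 90, none passed (16 lower adjusted over the list alone). Their median was -0.75 (camera adjusted p = 5.8e-09, adjusted p = 0.811 with an estimated correlation), and -0.70 with slide fixed and -2.24 to -0.073 within slides. The cilium regulator Foxj1 (-0.88 ± 0.22, adjusted p = 0.0807) and Rsph1 (-0.78 ± 0.24, adjusted p = 0.0869) did not pass. Much of this rested on GO replicate 2, the array with the fewest spots above background (26.1%), without which the list median was -0.40, Foxj1 at -0.60 and Rsph1 at -0.51, with 0 genes in limma and 812 at an unadjusted p under 0.05. Over the 3 slides with both groups 0 genes passed with slide as a fixed block, and leaving out 1 array gave 24 without GO replicate 1, 392 without GO replicate 3, 1970 without GO replicate 4, 4 without control replicate 3, 858 without GO replicate 5, 3 without control replicate 4 and 255 without GO replicate 6.

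With 54 µg of GO at day 90 (5 and 5 arrays) limma also gave 0 genes, with 275 at an unadjusted p under 0.05 and 0 with slide as a fixed block over 3 slides. Among 9 erythroid genes tested, none passed (2 lower adjusted over the list alone). Their median was -0.44 (camera adjusted p = 1.6e-05, adjusted p = 0.0653 with an estimated correlation), and -0.44 with slide fixed and -0.56 to -0.21 within slides. Bpgm (-0.61 ± 0.21, adjusted p = 1) and Saa3 (0.25 ± 0.45, adjusted p = 1) did not pass. With 18 µg of rGO at day 90 (5 and 5 arrays), the immediate early gene Egr1 differed by 1.14 ± 0.35, adjusted p = 1, and limma gave 0 genes, 305 at an unadjusted p under 0.05 and 0 with slide as a fixed block over 2 slides.

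With 54 µg of rGO at day 90 (5 and 5 arrays), Gbp4 rose by 1.00 ± 0.31, the stress gene Gadd45b by 0.50 ± 0.16 and the B cell gene Cd22 by 0.46 ± 0.13, with overlapping arrays for Gbp4 and Cd22. The matrix protease Mmp3 fell by 0.61, the heat shock gene Dnajb1 by 0.53 and Gclm, a subunit of the glutathione-making enzyme, by 0.39. Arrays also overlapped for Mmp3, and Gbp4, Gadd45b, Mmp3 and Dnajb1 did not pass with slide as a fixed block. In limma, 909 of 15541 genes passed, 686 higher and 223 lower, and 149 of the higher and 64 of the lower genes were apart in every array (chance 0.794%). 528 genes passed with slide as a fixed block, and 99.4% of the called genes had the same sign within each of the 2 slides that held both groups. The count was 34 without control replicate 1, 398 without rGO replicate 2, 178 without control replicate 2, 234 without control replicate 3, 379 without rGO replicate 5, 209 without control replicate 4 and 2217 without control replicate 5, and 0 in limma with Neat1 as a covariate (375 at an unadjusted p under 0.05), where Gbp4 was at -0.031.

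The highest rGO dose at day 90 (5 and 5 arrays) differed from vehicle in 1 gene, Mmp12, the elastase of macrophages, which rose by 1.05 ± 0.20, adjusted p = 0.0143, with overlapping arrays. Its change was 1.09 with slide fixed and 0.74 to 1.83 within slides, and 423 genes had an unadjusted p under 0.05 in limma. The macrophage genes Gpnmb (1.71 ± 0.47, adjusted p = 0.723) and Ctsk (0.90 ± 0.22, adjusted p = 0.422) and Saa3 (0.29 ± 0.45, adjusted p = 0.999) did not pass. Of 26 lysosome and lipid-laden macrophage genes tested at day 90, 1 rose and 25 did not pass (3 higher adjusted over the list alone). Their median was 0.13 (camera adjusted p = 1.0e-06, adjusted p = 0.68 with an estimated correlation), the median being 0.056 without rGO replicate 1 and 0.23 without control replicate 4. Leaving out 1 array gave 0 without control replicates 1, 2 and 3 and rGO replicates 1, 2 and 4 left out in turn and 6 without control replicate 4.

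The rGO dose trend at day 90 called 7 genes in limma, all rising with dose per 162 µg. They were Gpnmb (2.01 ± 0.43), Mmp12 (1.19 ± 0.18), Cxcr1 (1.18 ± 0.24), the bone and macrophage protease Ctsk (1.08 ± 0.20) and, named after their values were seen, Cd177, Npy and Gm17019. Gpnmb, Npy and Gm17019 did not pass with slide as a fixed block. Of 26 lysosome and lipid-laden macrophage genes tested in the day 90 trend, 3 rose and 23 did not pass (5 higher adjusted over the list alone). Their median was 0.18 (camera adjusted p = 5.4e-12, adjusted p = 0.0504 with an estimated correlation), the median being 0.081 without rGO 162 µg replicate 1. Slide as a fixed block gave 4 genes, fitting only these groups 0 in limma (786 at an unadjusted p under 0.05), and the count was 1 without rGO 162 µg replicate 1, 3 without control replicates 2 and 3 left out in turn, 4 without rGO 18 µg replicate 3, rGO 162 µg replicate 4 and control replicate 5 left out in turn and 12 without control replicate 4.

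Between GO and rGO at 54 µg and day 90 (5 and 5 arrays), GO was higher in Gpnmb (1.59 ± 0.47), Acta2 (1.03 ± 0.29), Hspa1a (0.60 ± 0.18), the lysosomal protease Ctsb (0.55 ± 0.13) and Gclm (0.35 ± 0.10), and lower in the lymphocyte gene Cd5 (-0.89 ± 0.22). Arrays overlapped for Gpnmb, Hspa1a and Cd5. Gpnmb, Hspa1a and Gclm did not pass with slide as a fixed block, Gpnmb being at 1.45 with slide fixed and -0.082 to 0.42 within slides. Of 26 lysosome and macrophage genes tested at 54 µg, 2 were higher with GO and 24 did not pass (3 higher adjusted over the list alone). Their median was 0.19 (camera adjusted p = 0.00404, adjusted p = 0.546 with an estimated correlation). In limma, 660 of 15541 genes passed, 157 higher and 503 lower, and 69 of the higher and 102 of the lower genes were apart in every array (chance 0.794%). 540 genes passed with slide as a fixed block, and 99.7% of the called genes had the same sign within each of the 2 slides that held both groups, with a lysosome median of 0.19 with slide fixed and -0.095 to 0.16 within slides. The count was 0 in limma with only the 2 groups fitted (3035 at an unadjusted p under 0.05), 202 without rGO replicate 1, 1668 without GO replicate 1, 250 without rGO replicate 2, 280 without GO replicate 2, 277 without rGO replicate 3, 219 without rGO replicate 4, 2 without GO replicate 3, 0 without GO replicate 4 and rGO replicate 5 left out in turn and 23 without GO replicate 5, and 0 in limma with Neat1 as a covariate (420 at an unadjusted p under 0.05).

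At 18 µg and day 90 (6 GO, 5 rGO arrays), GO was lower than rGO in the endothelial genes Kdr (-0.81 ± 0.24) and Cdh5 (-0.76 ± 0.23), in Foxj1 (-0.78 ± 0.22) and in the interferon-induced Gbp2 (-0.59 ± 0.15), and higher in Dnajb1 (0.64 ± 0.16) and Cdkn1a (0.57 ± 0.17), with overlapping arrays for each of these. Without GO replicate 2, Kdr, Cdh5 and Foxj1 were at -0.39, -0.36 and -0.50. Signs differed between the 2 slides for Foxj1 (-0.99 to 0.24), Dnajb1 (-0.17 to 1.32) and Cdkn1a (-0.12 to 0.81). Of 17 endothelial markers tested, 2 were lower with GO and 15 did not pass (15 lower adjusted over the list alone). Their median was -0.63 (camera adjusted p = 9.5e-07, adjusted p = 0.997 with an estimated correlation), and -0.61 with slide fixed and -0.25 to -0.051 within slides, the median being -0.19 without GO replicate 2. Cdh5 did not pass without the arrays of the older protocol. In limma, 573 of 15541 genes passed, 181 higher and 392 lower, and 12 of the higher and 35 of the lower genes were apart in every array (chance 0.433%). 396 genes passed with slide as a fixed block, and 61.4% of the called genes had the same sign within each of the 2 slides that held both groups. The count was 0 in limma with only the 2 groups fitted (985 at an unadjusted p under 0.05), 0 without GO replicate 2, 358 without rGO replicate 2, 1271 without GO replicate 3, 52 without rGO replicate 3, 7 without rGO replicate 4, 3020 without GO replicate 4, 1 without rGO replicate 5, 1416 without GO replicate 5 and 339 without GO replicate 6.

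Carbon black at 162 µg was compared with vehicle at day 90 (5 and 5 arrays) as the particle reference at the latest time. Saa3 rose by 3.00 ± 0.45, Saa1 by 1.39 ± 0.28 and Lcn2 by 1.29 ± 0.24. The monocyte attractants Ccl7, Ccl8 and Ccl12 rose by 1.57 ± 0.46, 1.40 ± 0.43 and 1.18 ± 0.29. Trem2, a lipid-sensing receptor of macrophages, rose by 1.69 ± 0.35, the scavenger receptor Msr1 by 0.84 ± 0.19, Ctsd by 0.89 ± 0.19, Cd300lf by 1.81 ± 0.36 and Gdf15, a stress-induced cytokine, by 1.13 ± 0.27. The interferon-stimulated Oas2, Stat2 and Oasl2 rose by 1.73 ± 0.33, 1.14 ± 0.20 and 1.05 ± 0.25. The clock output genes Dbp, Per2 and Per3 rose by 2.50 ± 0.38, 1.55 ± 0.24 and 1.45 ± 0.22, and their activator Arntl fell by 1.60. Snhg16 rose by 1.30, Hnrnpa2b1 by 1.11, Csf2 by 0.98 and the proliferation marker Mki67 by 0.79. Falls included Krtap17-1 (-1.13), Pon1 (-1.12), Fos (-1.08), Asgr1 (-1.07), Mmp3 (-0.97), H2bc6 (-0.85), the fibroblast receptor Pdgfra (-0.82) and Tnfrsf19 (-0.82). Mmp12 differed by 0.37 ± 0.20, adjusted p = 0.222. Every CB array lay apart from every control array for Cd300lf, Stat2, Oasl2, Snhg16, Hnrnpa2b1, Csf2, Mki67, Krtap17-1, Pon1, Fos, Asgr1, H2bc6 and Tnfrsf19, and the arrays of the groups overlapped for the other genes named here.

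Of 29 interferon-stimulated genes tested, 14 rose and 15 did not pass (21 higher adjusted over the list alone). Their median was 0.76 (camera adjusted p = 3.7e-13, adjusted p = 0.293 with an estimated correlation), and 0.69 with slide fixed and 0.27 to 1.27 within slides. Of 26 lysosome and lipid-laden macrophage genes tested, 11 rose, 1 fell and 14 did not pass (13 higher and 1 lower adjusted over the list alone). Their median was 0.38 (camera adjusted p = 4.4e-06, adjusted p = 0.293 with an estimated correlation), and 0.37 with slide fixed and 0.19 to 0.74 within slides. Of 22 monocyte attractants tested, 9 rose and 13 did not pass (10 higher adjusted over the list alone). Their median was 0.61 (camera adjusted p = 1.9e-04, adjusted p = 0.293 with an estimated correlation), and 0.67 with slide fixed and 0.52 to 1.19 within slides, the median being 0.93 without control replicate 4. Of 17 circadian clock genes tested, 11 rose, 4 fell and 2 did not pass (11 higher and 4 lower adjusted over the list alone). Their median was 0.75 (camera adjusted p = 1.0e-05, adjusted p = 0.0842 with an estimated correlation), and 0.80 with slide fixed and -0.029 to 1.04 within slides. In limma, 1673 of 15541 genes passed, 1029 higher and 644 lower, and 130 of the higher and 126 of the lower genes were apart in every array (chance 0.794%). 1103 genes passed with slide as a fixed block, and 78.1% of the called genes had the same sign within each of the 3 slides that held both groups, with Dbp at 2.50 with slide fixed and -0.63 to 3.64 within slides, Per3 at 1.45 with slide fixed and -0.029 to 2.62 within slides and Arntl at -1.59 with slide fixed and -2.63 to 0.40 within slides. With only the 2 groups fitted, limma gave 0 genes (3999 at an unadjusted p under 0.05). The count was 1013 without CB replicate 1, 465 without control replicate 1, 935 without control replicate 2, 729 without control replicate 3, 772 without CB replicate 4, 741 without CB replicate 5 and 3041 without control replicate 5, and 86 with Neat1 and 1 with the clock score as a covariate. Among simulated values with independent normal noise, 94% of 2-fold changes were recovered, with 3.21% of calls false.

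**Figure D4:**
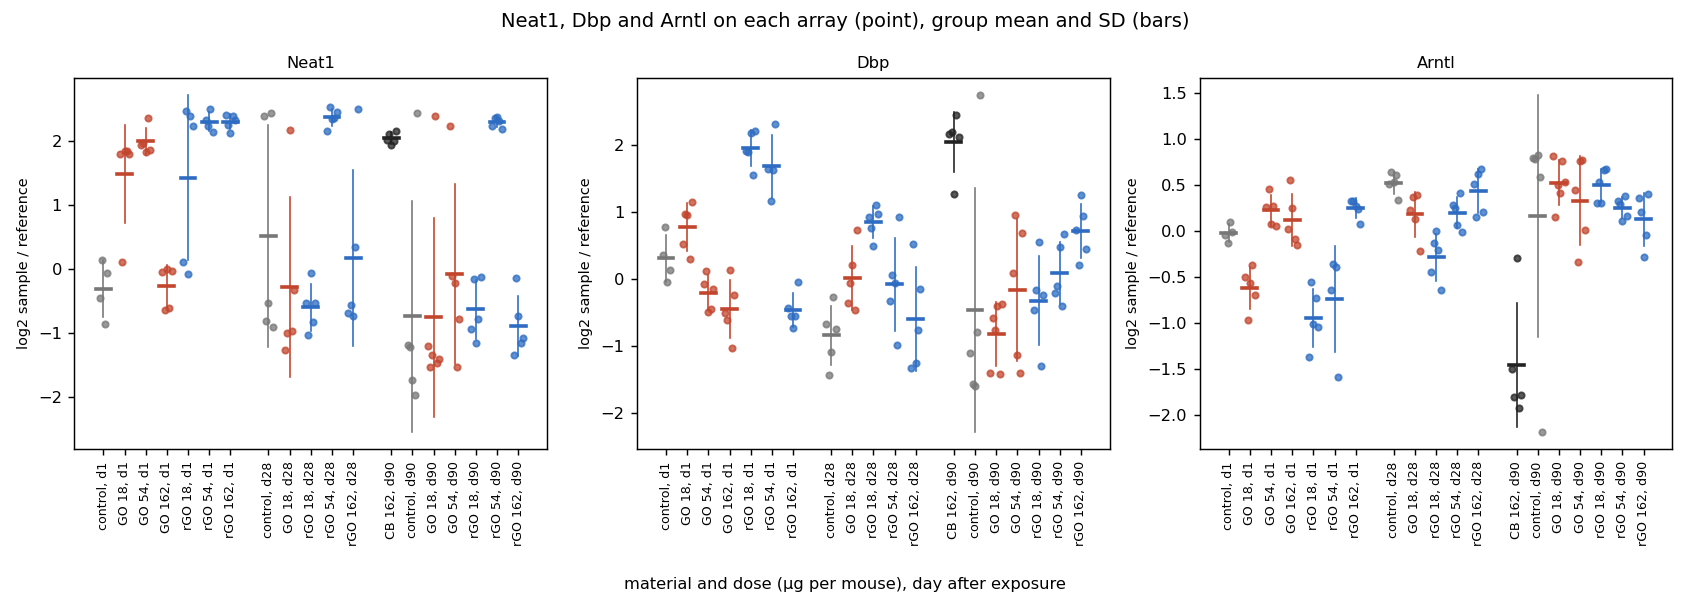
Log2 ratio to the reference RNA of Neat1, Dbp and Arntl on each array, by group, with the group mean and SD. Neat1 rose by 2.58 at rGO 162 µg on day 1, and with CB at day 90 Dbp rose by 2.50 and Arntl fell by 1.60.

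CB and rGO were compared at 162 µg and day 90 (5 and 5 arrays) to ask whether particles differed at the same mass. CB was higher in Saa3 by 2.71 ± 0.45, Oas2 by 2.42 ± 0.33, Cxcl10 by 2.04 ± 0.47, Ifit1 by 1.59 ± 0.28, Per3 by 1.48 ± 0.22 and Stat2 by 1.42 ± 0.20. It was lower in Egr1 (-1.72 ± 0.35), Arntl (-1.62 ± 0.25), Fos (-1.55 ± 0.32), Acta2 (-1.18 ± 0.29), the elastin crosslinker Loxl1 (-0.95 ± 0.22), Tagln (-0.88 ± 0.23) and Mmp12 (-0.68 ± 0.20), the last at -0.72 with slide fixed and -0.73 to 0.35 within slides. Arrays overlapped for Saa3, Loxl1 and Mmp12. Of 29 interferon-stimulated genes tested, 24 were higher with CB and 5 did not pass (26 higher adjusted over the list alone). Their median was 0.99 (camera adjusted p = 6.3e-19, adjusted p = 0.225 with an estimated correlation), and 0.89 with slide fixed and 0.94 to 1.70 within slides. In limma, 2769 of 15541 genes passed, 1598 higher and 1171 lower, and 1059 of the higher and 555 of the lower genes were apart in every array (chance 0.794%). 2250 genes passed with slide as a fixed block, and 99.2% of the called genes had the same sign within each of the 2 slides that held both groups. The count was 1789 without CB replicate 4 and 1736 without CB replicate 5, and 149 with Neat1 and 171 with the clock score as a covariate.

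Whether the effect of 162 µg of rGO changed with time was tested as a difference between days (5 rGO arrays per day, with 4 control arrays at day 1 and 5 at days 28 and 90). Against day 1, the effect at day 28 was lower for S100a8 (-2.83 ± 0.71), Klra8 (-2.25 ± 0.54) and Chil3 (-2.17 ± 0.65, not passing with slide as a fixed block), and higher for Acta2 (1.81 ± 0.42). Saa3 differed by -0.62 ± 0.65, adjusted p = 0.662. Of 16 natural killer cell markers tested, 9 had a lower effect and 7 did not pass (14 lower adjusted over the list alone). Their median was -1.11 (camera adjusted p = 5.3e-11, adjusted p = 0.389 with an estimated correlation). Of 24 alveolar macrophage markers tested, 5 had a lower effect and 19 did not pass (13 lower adjusted over the list alone). Their median was -0.97 (camera adjusted p = 2.8e-06, adjusted p = 0.389 with an estimated correlation). In limma, 684 of 15541 genes passed, 180 higher and 504 lower, and 432 with slide as a fixed block. The count was 37 without day 28 control replicate 1, 449 without day 1 rGO replicate 1, 1 without day 28 rGO replicates 1 and 3 and day 28 control replicate 4 left out in turn, 328 without day 28 rGO replicate 2, 1088 without day 28 control replicate 3, 0 without day 1 control replicate 3, 117 without day 1 rGO replicate 4, 274 without day 1 control replicate 4, 1517 without day 28 rGO replicate 5 and 1133 without day 28 control replicate 5, day 28 rGO replicate 3 being the array with conflicting labels. It was 0 in limma without the arrays of the older protocol (1826 at an unadjusted p under 0.05), which took 1 rGO array from each day and 1 control array from day 28, and 0 in limma with Neat1 as a covariate (736 at an unadjusted p under 0.05).

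At day 90 the effect was lower than at day 1 for Chil3 (-2.75 ± 0.65) and Klra8 (-2.26 ± 0.54) and higher for Acta2 (1.73 ± 0.42), and Saa3 differed by -1.23 ± 0.66, adjusted p = 0.261. Among 24 alveolar macrophage markers tested, 7 had a lower effect and 17 did not pass (13 lower adjusted over the list alone). Their median was -1.02 (camera adjusted p = 1.1e-05, adjusted p = 0.718 with an estimated correlation). In limma, 820 of 15541 genes passed, 225 higher and 595 lower, and 349 with slide as a fixed block. The count was 491 without day 1 rGO replicate 1, 0 without day 1 control replicate 3, 283 without day 1 rGO replicate 4, 250 without day 1 control replicate 4, 417 without day 90 rGO replicate 3, 255 without day 90 rGO replicate 5 and 29 without day 90 control replicate 5, and 0 in limma with Neat1 as a covariate (1310 at an unadjusted p under 0.05).

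**Figure D5:**
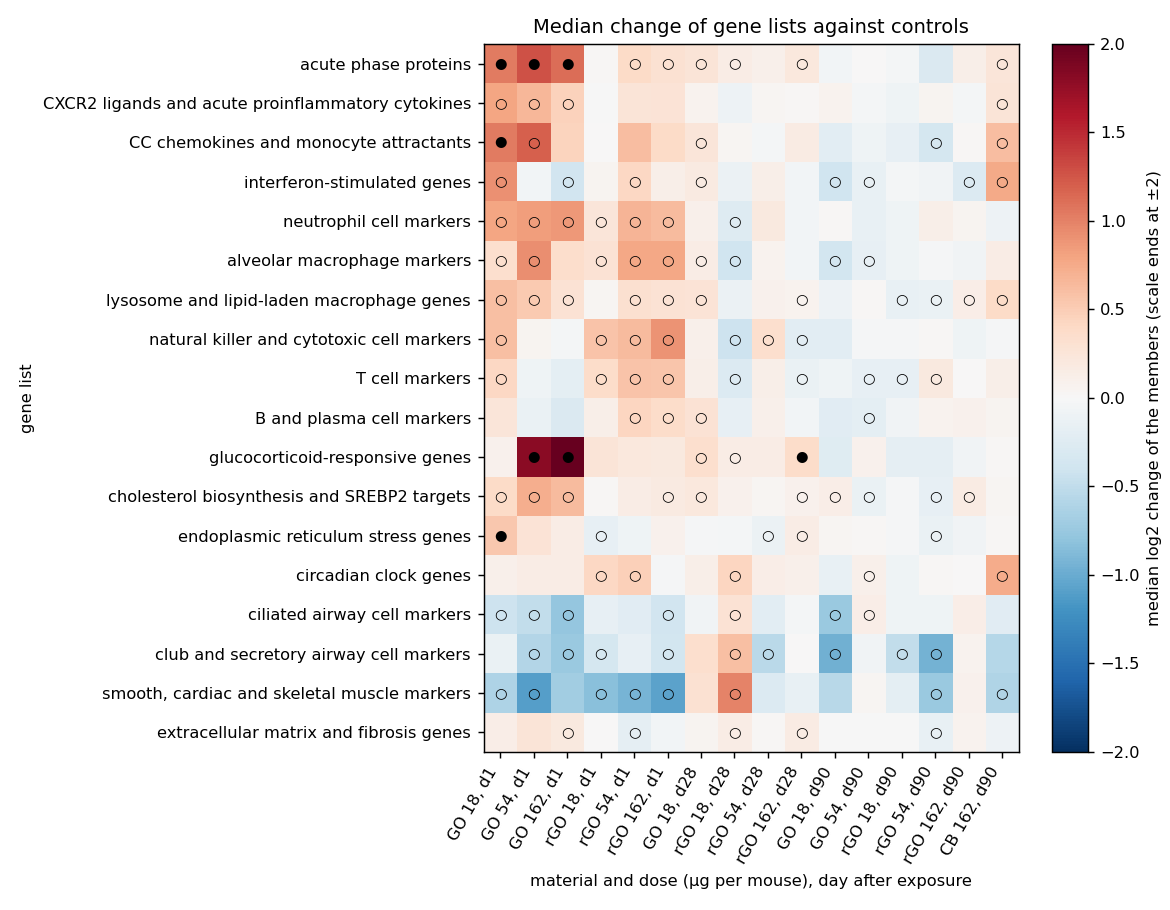
Median log2 change of 18 gene lists (vertical) in each of 16 comparisons with the control of the same day (horizontal), in colour. Filled circles mark lists called with both the preset and the estimated correlation, and open circles those called with the preset alone.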

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

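Tests of slide and of a state shared with control arrays for Neat1, time of day for clock genes, and scanner file order were chosen only after the result was seen.

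Within groups of 4 to 6 arrays, 45 of 467 gene and group pairs (9.64%) held an array far from the others, where chance gives about 1 in 20. Their log2 ratios to the reference RNA follow. On control day 90 replicate 4 they were Ccl12 (1.33), Ccl8 (4.46), Ctsd (1.71), Ctsk (3.48), Cxcr1 (2.32), Egr1 (-1.01), Gdf15 (-1.08), Gpnmb (-0.99), Lcn2 (3.02) and Trem2 (0.13). On control day 90 replicate 5 they were Arntl (-2.18), Dbp (2.74), Hnrnpa2b1 (-0.16), Mmp3 (-0.65), Per2 (1.70), Per3 (1.70), Snhg16 (-1.65) and Stat2 (0.89). On control day 1 replicate 1 they were Ccl7 (-3.75), Cdkn1a (-1.14), Cr2 (2.43), Saa1 (-0.22) and Saa3 (-2.92). On CB 162 µg day 90 replicate 3 they were Arntl (-0.29), Dbp (1.28) and Loxl1 (0.29). On GO 18 µg day 90 replicate 2 they were Cdh5 (3.95), Gbp2 (1.28) and Kdr (3.56). On rGO 162 µg day 1 replicate 2 they were Gsta4 (-0.019) and Klra8 (2.52). On rGO 162 µg day 28 replicate 5 they were Lcn2 (2.97) and Saa3 (-0.76). Single values apart were Acta2 (0.022) on rGO 54 µg day 1 replicate 2, Aldh1a1 (5.00) on rGO 162 µg day 1 replicate 4, Atf3 (-0.005) on GO 18 µg day 28 replicate 2, Ccl17 (4.19) on GO 18 µg day 1 replicate 4, Ccn2 (0.75) on control day 1 replicate 2 and Ctsk (3.87) on rGO 162 µg day 90 replicate 1. Others were Gclc (4.06) on GO 162 µg day 1 replicate 4, Kdr (5.74) on rGO 18 µg day 90 replicate 1, Klra8 (3.31) on rGO 162 µg day 90 replicate 4, Krt19 (2.73) on GO 162 µg day 1 replicate 5, S100a8 (5.14) on rGO 162 µg day 1 replicate 1 and Saa3 (0.60) on rGO 54 µg day 1 replicate 4.

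The change of the 162 µg rGO effect from day 1 passed in 684 genes at day 28 and 820 at day 90. Without the 6 older protocol arrays these were 0 in limma (1826 at an unadjusted p under 0.05) and 702. Neither kept any without day 1 control replicate 3 or with Neat1 as a covariate.

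The long noncoding RNA Neat1, and genes that vary with it, differed between groups and also among arrays of 1 group. Against slide as the source, the change of Neat1 at rGO 162 µg day 1 was 2.53 ± 0.69 with slide as a fixed block, against 2.58 ± 0.64. Against signal over background, it was 2.57 ± 0.64 with the percent of Cy5 spots above background as a covariate, where 2124 genes passed. Across 15428 genes, which are not independent replicates, the change at rGO 162 µg day 1 correlated with the slope on Neat1 among the 10 control arrays of days 28 and 90 (Pearson r = 0.575, Spearman rho = 0.517). A state of tissue or RNA that also arises in control lungs may therefore underlie part of the rGO response at day 1, and an effect of the material on that state stays open.

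Clock genes differed between CB and control at day 90. Across 16 clock genes, which are not independent replicates, the CB change correlated with the slope on Dbp within other groups (r = 0.845). Any clock shift gives this, so time of day of sampling stays open. Against stress, 15 glucocorticoid-responsive genes, also not independent, had a median change of 0.019 and mean of 0.175 (95% interval over genes -0.125 to 0.474). The Saa3 change was 2.09 ± 0.55 with the clock score as a covariate and 3.00 ± 0.45 without. The clock state is thus unlikely to be its whole source. Yet the call ended (adjusted p = 0.43, 2.0e-09 to 1 over the alternatives), as did nearly all CB calls against control. A CB effect on the clock was not tested.

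By correlation of at least 0.9, 55 scanner arrays matched the value table column of their own sample, 38 that of another sample and 1 none. If scanner files lay under wrong samples, the value table order would give tighter groups. Its median variance within groups was 0.0494 against 0.0386 in scanner order, a ratio of 1.28, and random orders gave 0.0448 to 0.0498. This argues against misplaced scanner files and suggests that the columns of the value table were reordered, for which no biological explanation was tested.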

How the results depend on the processing

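Tests with Neat1 or the clock score as a covariate, scan day as the block, the value table in scanner order, and without doubted arrays or the possibly swapped pair were chosen only after the result was seen. Counts of genes past the threshold in limma are against the control of the same day unless 2 materials are named, with doses in µg. They are given wherever an alternative moved them by over 1.5 times. A trended robust variance moved none of the 29 counts by that much. Quantile normalization leaves log ratios unchanged and is not counted below.

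With the authors' value table as labelled, the count was 920 for GO 18 day 1, 4166 for GO 54 day 1, 2471 for GO 162 day 1, 0 for rGO 54 day 1, rGO 162 day 1, rGO 18 day 28, rGO 54 day 90, rGO 162 day 90, CB 162 day 90, the rGO trend day 1, the rGO trend day 90, GO minus rGO 18 day 90, GO minus rGO 54 day 90, CB minus rGO 162 day 90, the day 28 minus day 1 effect as well as the day 90 minus day 1 effect, 1 for rGO 54 day 28, 3996 for the GO trend day 1 and 2139 for GO minus rGO 54 day 1. A fold of at least 1.5 left 1213 for GO 18 day 1, 2713 for GO 54 day 1, 2049 for GO 162 day 1, 738 for rGO 54 day 1, 838 for rGO 162 day 1, 21 for rGO 18 day 28, 329 for rGO 54 day 90, 528 for CB 162 day 90, 2033 for the GO trend day 1, 456 for the rGO trend day 1, 666 for GO minus rGO 18 day 1, 1486 for GO minus rGO 54 day 1, 2528 for GO minus rGO 162 day 1, 174 for GO minus rGO 18 day 90, 270 for GO minus rGO 54 day 90 and 845 for CB minus rGO 162 day 90. An adjusted p under 0.01 left 1952 for GO 18 day 1, 364 for rGO 54 day 1, 671 for rGO 162 day 1, 2 for rGO 18 day 28, 0 for rGO 54 day 28, rGO 162 day 90 as well as GO minus rGO 54 day 90, 123 for rGO 54 day 90, 521 for CB 162 day 90, 182 for the rGO trend day 1, 3 for the rGO trend day 90, 1029 for GO minus rGO 18 day 1, 2679 for GO minus rGO 54 day 1, 4 for GO minus rGO 18 day 28 and the day 90 minus day 1 effect, 5 for GO minus rGO 18 day 90, 1266 for CB minus rGO 162 day 90 and 1 for the day 28 minus day 1 effect. With only genes above background on all arrays (fewer genes tested), the count was 4147 for GO 54 day 1, 3607 for GO 162 day 1, 1255 for rGO 162 day 1, 3 for GO 18 day 28, 0 for rGO 54 day 28 and rGO 162 day 90, 594 for rGO 54 day 90, 1082 for CB 162 day 90, 4076 for the GO trend day 1, 1 for the rGO trend day 90, 3820 for GO minus rGO 162 day 1, 432 for GO minus rGO 54 day 90 and 1816 for CB minus rGO 162 day 90. Fitting only the days compared gave 2 for rGO 18 day 1, 19 for GO 18 day 28, 157 for rGO 18 day 28, 1 for rGO 54 day 28, 3 for rGO 162 day 28 and the rGO trend day 90, 434 for rGO 54 day 90, 0 for rGO 162 day 90 and GO minus rGO 18 day 90, 203 for GO minus rGO 18 day 28 and 67 for GO minus rGO 54 day 90. Fitting only the groups compared gave 4 for GO 18 day 28, 101 for rGO 18 day 28, 0 for rGO 54 day 28, CB 162 day 90, the rGO trend day 90, GO minus rGO 18 day 90 as well as GO minus rGO 54 day 90, 287 for rGO 54 day 90, 460 for the rGO trend day 1, 182 for the day 28 minus day 1 effect and 1253 for the day 90 minus day 1 effect. Cy5 alone gave 1012 for rGO 54 day 1, 1 for GO 18 day 28 and rGO 54 day 28, 26 for rGO 18 day 28, 263 for rGO 54 day 90, 2 for rGO 162 day 90, 863 for CB 162 day 90, 123 for GO minus rGO 18 day 28, 13 for GO minus rGO 18 day 90 and 294 for GO minus rGO 54 day 90. Neat1 as a covariate gave 0 for rGO 54 day 1, rGO 162 day 1, rGO 54 day 28, rGO 54 day 90, GO minus rGO 54 day 90, the day 28 minus day 1 effect as well as the day 90 minus day 1 effect, 1 for GO 18 day 28, 16 for rGO 18 day 28, 10 for GO 18 day 90, 86 for CB 162 day 90, 21 for the rGO trend day 1, 122 for GO minus rGO 18 day 28, 985 for GO minus rGO 18 day 90 and 149 for CB minus rGO 162 day 90. The clock score as a covariate gave 493 for rGO 54 day 1, 2 for GO 18 day 28, 582 for rGO 18 day 28, 0 for rGO 54 day 28, 1 for CB 162 day 90, 2214 for the rGO trend day 1, 94 for GO minus rGO 18 day 28, 171 for CB minus rGO 162 day 90, 1466 for the day 28 minus day 1 effect and 1677 for the day 90 minus day 1 effect. Leaving out CB day 90 replicate 3 and rGO 54 µg day 1 replicate 4 gave 996 for rGO 54 day 1 and 5 for GO 18 day 28. The probe mean gave 3 for GO 18 day 28 and 1 for rGO 54 day 28. Leaving out GO 18 µg day 90 replicates 2 and 4 and rGO 54 µg day 90 replicate 4 gave 6 for GO 18 day 28, 77 for rGO 18 day 28, 131 for GO minus rGO 18 day 28, 1079 for the day 28 minus day 1 effect and 1265 for the day 90 minus day 1 effect. The value table in scanner order gave 1 for GO 18 day 28, 180 for GO minus rGO 18 day 28, 2 for GO minus rGO 18 day 90, 1070 for the day 28 minus day 1 effect and 1264 for the day 90 minus day 1 effect. No slide block gave 22 for rGO 18 day 28, 1 for rGO 54 day 28, 228 for GO minus rGO 18 day 90 and 358 for GO minus rGO 54 day 90. Slide as a fixed block gave 23 for rGO 18 day 28, 0 for rGO 54 day 28, 528 for rGO 54 day 90, 1103 for CB 162 day 90, 4 for the rGO trend day 90, 29 for GO minus rGO 18 day 28, 432 for the day 28 minus day 1 effect and 349 for the day 90 minus day 1 effect. Leaving out normexp gave 0 for rGO 54 day 28 and 365 for GO minus rGO 18 day 90. No filter gave 1 for rGO 54 day 28, 365 for GO minus rGO 18 day 90, 405 for GO minus rGO 54 day 90 and 522 for the day 90 minus day 1 effect. Scan day as the block gave 1 for rGO 54 day 28. Processed signals gave 1 for GO 18 day 90, 0 for rGO 162 day 90, 4 for the rGO trend day 90, 114 for GO minus rGO 18 day 28 and 95 for GO minus rGO 18 day 90. Leaving out the 6 arrays of the older protocol gave 1 for rGO 18 day 1, 13 for rGO 18 day 28, 48 for rGO 54 day 28, 8 for GO minus rGO 18 day 28 and 0 for the day 28 minus day 1 effect. Leaving out the array with conflicting labels gave 1 for the day 28 minus day 1 effect.

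Leaving out each array in turn gave 0 to 2 for rGO 18 day 1, 455 to 1451 for rGO 54 day 1, 729 to 1787 for rGO 162 day 1, 0 to 5 for GO 18 day 28, 2 to 50 for rGO 18 day 28, 0 to 652 for rGO 54 day 28, 0 to 1970 for GO 18 day 90, 34 to 2217 for rGO 54 day 90, 0 to 6 for rGO 162 day 90, 465 to 3041 for CB 162 day 90, 141 to 1586 for the rGO trend day 1, 1 to 12 for the rGO trend day 90, 1307 to 1918 for GO minus rGO 18 day 1, 0 to 185 for GO minus rGO 18 day 28, 0 to 3020 for GO minus rGO 18 day 90, 0 to 1668 for GO minus rGO 54 day 90, 1736 to 3218 for CB minus rGO 162 day 90, 0 to 1517 for the day 28 minus day 1 effect and 0 to 1120 for the day 90 minus day 1 effect. It moved no count by over 1.5 times for GO 18 day 1 (2505 to 3534), GO 54 day 1 (5607 to 6602), GO 162 day 1 (4286 to 5495), rGO 162 day 28 (0 to 0), GO 54 day 90 (0 to 0), rGO 18 day 90 (0 to 0), the GO trend day 1 (5671 to 6513), the rGO trend day 28 (0 to 0), GO minus rGO 54 day 1 (3575 to 4235) and GO minus rGO 162 day 1 (5870 to 6175). Of named genes, Gbp4 in rGO 54 day 90 turned to -0.031 with Neat1 as a covariate. With CB at day 90, Dbp turned to -0.069 in the value table as labelled and to -0.016 with the clock score, Mmp3 to 0.030 and Hnrnpa2b1 to -0.007 in the value table. Over 5244 values of named genes under other settings, 4721 kept direction and side of the threshold, 512 kept direction but no longer passed, 6 newly passed and 5 turned. With single arrays left out, 2538 of 2863 kept both, 314 no longer passed and 11 newly passed. Of 351 gene list calls, 19 held with an estimated correlation. Where an alternative left 0 genes, limma gave 102 to 3999 at an unadjusted p under 0.05, and 116 to 2844 where 1 array was left out. The value table as labelled puts 38 arrays under another sample than the scanner files do, so its groups hold other arrays. For the other moves the cause was not tested, apart from the stricter thresholds and filter, which call or test fewer genes. A strict filter gave no value for named genes below background on some array, and low signal limits what dim genes can show. No paired analysis was possible because the labels do not pair arrays.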

Other observations

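Of the tests in this part, the distances between arrays and leaving out doubted arrays were chosen only after the result was seen.

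The samples of each comparison were regrouped, in 100 splits drawn at random or all 35 where there were no more, and the real count over genes without missing values is given against the highest of the other splits. A share of 1 in 100 is the smallest that 100 splits can give, so it makes chance less likely without excluding it. The real split alone was that large among 100 for GO 18 µg day 1 (3389 against 1842), GO 54 µg day 1 (6581 against 5733), GO 162 µg day 1 (5482 against 4542), rGO 162 µg day 1 (1898 against 831), rGO 18 µg day 28 (43 against 2), the GO dose trend at day 1 (6434 against 3448), the rGO dose trend at day 1 (1177 against 162), the rGO dose trend at day 90 (7 against 2), GO minus rGO 18 µg day 1 (1952 against 786), GO minus rGO 54 µg day 1 (4147 against 3449), GO minus rGO 162 µg day 1 (6323 against 2965), GO minus rGO 54 µg day 90 (655 against 643) and CB minus rGO 162 µg day 90 (2750 against 1311). The share was also under 0.05 for rGO 54 µg day 1 (1604 against 0 genes in limma, 1 of 35), CB 162 µg day 90 (1667 against 3534, 3 of 100), GO minus rGO 18 µg day 28 (55 against 601, 4 of 100), the rGO effect at day 28 minus day 1 (678 against 1027, 4 of 100) and the rGO effect at day 90 minus day 1 (814 against 1143, 2 of 100). The share was not under 0.05, with 5 or more of 100 as large, for GO 18 µg day 28 (1 against 1012, 9 of 100), rGO 54 µg day 28 (4 against 593, 11 of 100), rGO 54 µg day 90 (904 against 1438, 5 of 100), rGO 162 µg day 90 (1 against 187, 12 of 100) and GO minus rGO 18 µg day 90 (569 against 2812, 11 of 100). Where limma gave 0 genes, all 100 splits are as large whatever the groups, so chance was not tested for rGO 18 µg day 1 (highest other 1377), rGO 162 µg day 28 (highest other 1152), GO 18 µg day 90 (highest other 3205), GO 54 µg day 90 (highest other 225), rGO 18 µg day 90 (highest other 0) and the rGO dose trend at day 28 (highest other 1020). Where another split called several times the real count, as for GO minus rGO 18 µg days 28 and 90, this points to a structure of the samples, for day 28 despite the share under 0.05. For CB and the rGO effects too, another split called more genes than the real one. At 54 µg of GO on day 1 the highest other split moved 8 of 9 arrays and so nearly reversed the real one. For rGO 54 µg at day 90 the split with 1438 genes exchanged rGO replicate 1 with control replicate 5, and for CB the split with 3534 genes, reversed, exchanged CB replicate 3 with control replicate 5.

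The arrays CB day 90 replicate 3 and rGO 54 µg day 1 replicate 4, which shared a slide, each lay nearer to the other's group, with RMS log2 distances of 0.327 to their own group against 0.237 and 0.364 against 0.241. With slide means removed these were 0.362 against 0.258 and 0.386 against 0.278. On their slides, the same held for rGO 54 µg day 90 replicate 2 and rGO 54 µg day 1 replicate 3 (0.331 against 0.268, 0.245 against 0.194) and for rGO 18 µg day 90 replicate 5 and rGO 162 µg day 90 replicate 4 (0.356 against 0.257, 0.295 against 0.216). The closest arrays of all, rGO 54 µg day 90 replicate 4 and GO 18 µg day 90 replicate 4, differed by 0.122, with 0.180 for the next pair and a median of 0.363 within groups. They shared a slide and came from 2 groups, so both could hold 1 RNA, which was not tested. Without GO replicate 4, GO 18 µg day 90 had 1970 genes rather than 0 and GO minus rGO 18 µg day 90 had 3020 rather than 573. Without rGO replicate 4, rGO 54 µg day 90 had 607 rather than 909 and GO minus rGO 54 µg day 90 had 219 rather than 660. Without both and GO 18 µg day 90 replicate 2 these were 0 (1972 at an unadjusted p under 0.05 in limma), 435, 1068 and 679.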
